A study of Homo sapiens with 6 samples.

How the data were processed

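SKOV3 ovarian carcinoma cells had been treated with sicontrol or siNRCP, 3 samples each, and 500 ng of total RNA per sample had been labelled as biotinylated cRNA and hybridised to Illumina BeadArrays. The deposited table of non-normalized values held bead intensity per probe and array, made by the authors with BeadStudio per the submitters' processing notes, with the software version not given in the sources used here. The deposited series matrix held log2 values that the authors had quantile normalized, with a median of 7.01 on each array; they differed from a log2 and quantile normalization of the intensity table by at most 0.065, and the target distribution they used is not stated. An aligner and a genome build do not apply to bead intensities. Names came from a reference table by Entrez identifier, and no coordinates are given. The genomic length of each gene (its span) was taken from the same table, of assembly GRCh38.p14, and 99.9% of the named genes above background had one.

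The plan, made before the data were examined, fixed the test, the gene lists, the named-gene rule and the alternatives. Because the intensity table carried no detection p-values, the fallback of that plan was used: normexp background correction with an offset of 50, quantile normalization and log2, with no detection filter. All 47231 probes were tested in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, siNRCP minus sicontrol, with no covariate, and a Benjamini-Hochberg adjusted p under 0.05 counted as a change. Of the probes 30113 carried 1 gene symbol, 8 several and 17110 none; 30074 were matched by Entrez identifier, 0 symbols were updated, and 20047 genes were named. Where a gene had several probes, the probe with the highest mean log2 signal over the 6 arrays stood for it, except among the genes with the largest change, which were ranked by probe.

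The 32 gene lists held 805 genes, of which 754 were measured. Each list was tested with camera at a preset correlation of 0.01 on 1 probe per gene, with Benjamini-Hochberg over the 32 lists and a minimum of 5 members. Camera with an estimated correlation and fry were run beside it. Counts of genes were given over all probes and adjusted over the list alone.

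Named genes were, first, the 10 largest increases and the 10 largest decreases among changed probes whose 3 siNRCP arrays all lay on 1 side of the 3 sicontrol arrays, with provisional gene names left out. Next came up to 2 changed genes per list and direction with the largest change. NRCP, CP, SLC2A1, HK1, HK2, GPI, ALDOA, PGK1, LDHA and TALDO1 were named whatever their values, and NRCP had no named probe; 1 further gene of the rule is not reported here. Genes named outside this rule are marked as chosen after their values were seen.

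The background level of an array was the 95th percentile of 437 probes of olfactory receptor genes, which are hardly expressed outside the nose, and a probe counted as above background when it exceeded that level on at least 3 arrays (20027 probes). In the report, a probe was not given a fold against a group in which it exceeded that level on 0 arrays. This level was chosen after the data had been seen and was not part of the main test.

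The fitting steps were tested on simulated data with known changes in 3 against 3 arrays. Of 67 probes changed by 1.5-fold 10.4% were recovered, of 67 changed by 2-fold 62.7%, and of 66 changed by 4-fold 100%, with 4 false calls among 47231 probes. The list step, on 20047 genes, recovered the 1 list that had been shifted and made 0 false calls. The simulated genes varied independently of each other. The simulation therefore says nothing of false calls in lists whose genes move together, as in oxidative phosphorylation (estimated correlation 0.67). Each simulated probe also had the same spread in both groups, with no difference between whole arrays. The 4 false calls are therefore no measure of false calls among the real probes.

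The alternatives tried were no background correction, an offset of 16, median scaling, cyclic loess, the series matrix values, eBayes with trend and robust options, array weights, the replicate number as a block, the mean of a gene's probes, a minimum of 1.5-fold, and leaving out each of the 6 arrays. A filter on the background level and a covariate for the main axis of spread among the sicontrol arrays were added after the data had been seen. Filters on detection p-values were left out because the intensity table carries none. A search for siRNA seed matches in transcripts was not done here.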

Results

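SKOV3 is an established human ovarian carcinoma cell line. Gene expression was measured in SKOV3 cells treated for 48 h with a control siRNA (sicontrol) or with an siRNA against NRCP (siNRCP), a long non-coding RNA whose gene is named after the ceruloplasmin gene. Total RNA from 3 sicontrol and 3 siNRCP samples was read on Illumina BeadArrays, 1 array per sample, with 47231 probes each. The mean raw intensity was 563, 556 and 555 on sicontrol arrays 1 to 3 and 554, 373 and 486 on siNRCP arrays 1 to 3, and between 39.8% and 44.0% of the probes lay above the background level on each array. The comparison asked which transcripts differ once NRCP is silenced, and, from what is known of work on NRCP, whether genes of glycolysis are among them. No probe carried the name NRCP, so the target itself is not analysed here and the depth of the knockdown could not be checked.

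The largest decreases in siNRCP were in a collagenase gene, chemokine genes, a lysosomal lipase gene, an intraflagellar transport gene and a cyclin gene. MMP1 (probe ILMN_1726448), a collagenase of the extracellular matrix, fell by 2.87 ± 0.16 log2 (SE, n = 3 per group; 7.30-fold; limma adjusted p = 0.0017), from 10.12 ± 0.28 (SD, n = 3) in sicontrol to 7.25 ± 0.17 in siNRCP. The chemokine genes CCL20 (ILMN_1657234) and CXCL8 (ILMN_1666733) fell by 2.57 ± 0.33 and 2.25 ± 0.28 log2 (adjusted p = 0.017 and 0.015), and the brighter CXCL8 probe fell by 1.51 ± 0.11 (adjusted p = 0.0041). CCNA1 (ILMN_2157099), which encodes a cyclin best known from the germ line, fell by 2.38 ± 0.10 log2, and SRSF7 (ILMN_1778836), a splicing factor, fell by 1.99 ± 0.09, both with an adjusted p of 0.0011. LIPA (ILMN_1718063), the lysosomal acid lipase, fell by 2.50 ± 0.16 log2 (adjusted p = 0.0027). The other genes among the 10 with the largest decrease were IFT25, a subunit of the intraflagellar transport machinery (-2.41 ± 0.38), BNIP3, a mitochondrial protein of mitophagy and cell death (-1.98 ± 0.16), CA2, a carbonic anhydrase (-1.95 ± 0.18; -1.77 ± 0.16 on its brighter probe), and SERPINA1, a secreted protease inhibitor (-1.92 ± 0.30; -1.71 ± 0.18 on its brighter probe). Their adjusted p was 0.032, 0.0059, 0.0075 and 0.031.

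The largest increases in siNRCP were in a glucosidase subunit gene, a secreted protease gene, a mitotic checkpoint gene and a chromatin regulator gene. GANAB (ILMN_1739441), a glucosidase subunit that trims glycans in the endoplasmic reticulum, rose by 2.34 ± 0.33 log2 (5.05-fold; limma adjusted p = 0.021), from 9.0 ± 0.12 to 11.34 ± 0.73 (SD, n = 3). The secreted protease gene PRSS23 rose by 1.99 ± 0.20 log2 (adjusted p = 0.0094), and ZW10, a protein of the mitotic checkpoint and of vesicle transport, rose by 1.80 ± 0.15 (adjusted p = 0.0075). TM4SF1 (ILMN_1770338), a surface protein of the tetraspanin-like family, rose by 1.67 ± 0.12 log2 (adjusted p = 0.0045) from a high level of 11.23 ± 0.09. ANKRD11, a chromatin regulator, rose by 1.80 ± 0.30 (adjusted p = 0.038), while its second probe lay at background. OSBPL5, a lipid transfer protein, rose by 1.78 ± 0.23 (1.46 ± 0.19 on its brighter probe), the galactosyltransferase gene B4GALT1 by 1.77 ± 0.29, the zinc finger genes ZNF845 and ZNF45 by 1.68 ± 0.20 and 1.66 ± 0.20, and TUFT1 by 1.64 ± 0.20. Their adjusted p lay between 0.015 and 0.035.

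**Figure D1:**
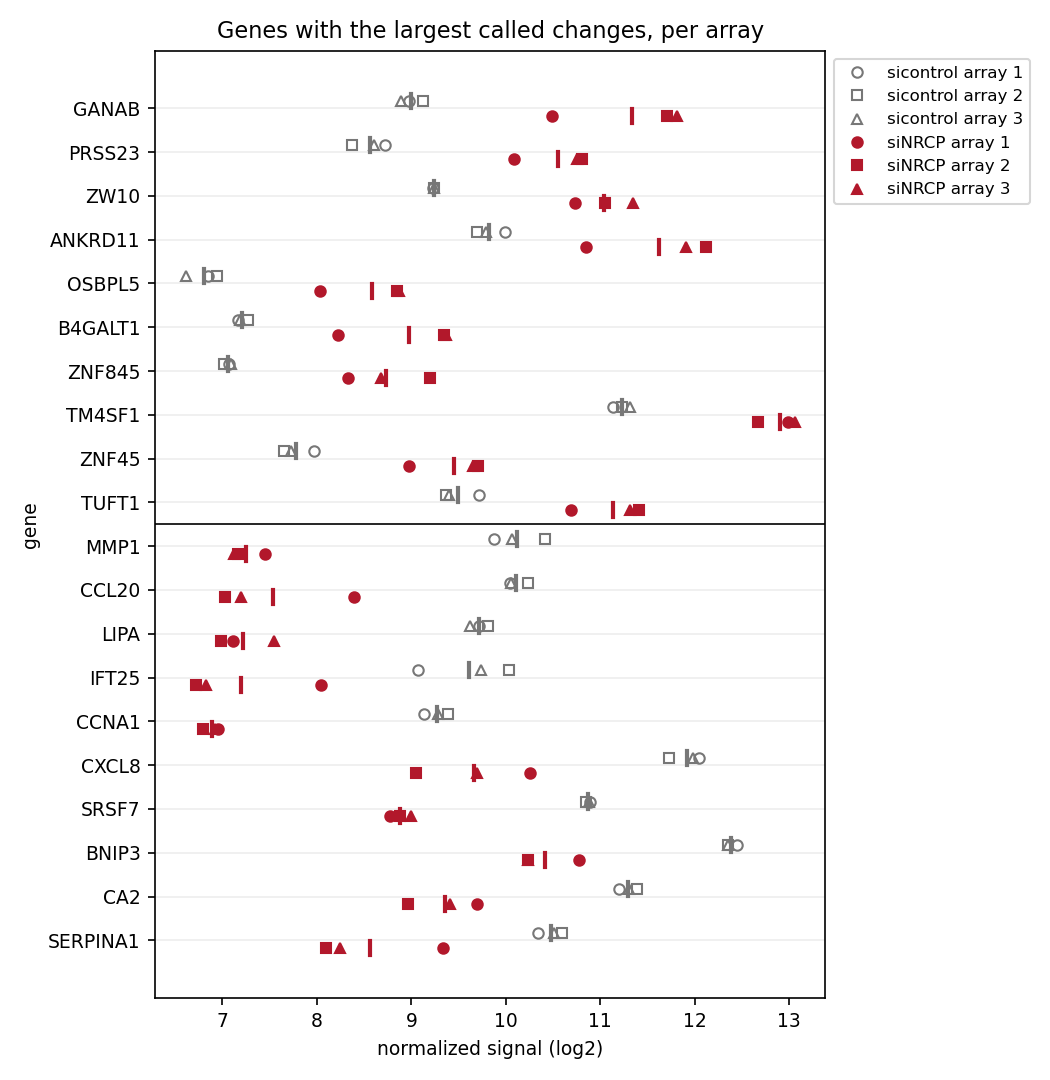
Normalized log2 intensity of the 10 genes with the largest increase and the 10 with the largest decrease in siNRCP, with 1 point per array in each group of 3 and a vertical bar at each group mean. For MMP1 the siNRCP arrays lay at a mean of 7.25 against 10.12 in sicontrol, and for GANAB at 11.34 against 9.0.

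In all, 781 of 47231 probes passed limma at a Benjamini-Hochberg adjusted p under 0.05, of which 349 (281 named genes) were higher and 432 (338 named genes) lower in siNRCP, and 97 carried no gene symbol. A change of at least 1.5-fold was seen on 701 of them, and 123 rose and 147 fell by at least 2-fold. The siNRCP and sicontrol arrays did not overlap on any of the 781, and all of them lay above background. Of all probes, 8424 (17.8%) did not overlap, where chance gives 10%. The count rested on the choice of arrays, and leaving out 1 array also weakens the test. Without sicontrol array 1, 2 or 3 the count was 12, 18 or 11, of which 0, 3 and 1 were higher in siNRCP. At an unadjusted limma p under 0.05 these fits held 5091, 4264 and 4232 probes, against 6505 with all arrays. Without siNRCP array 2 or 3 it was 188 or 39, of which 71 and 11 were higher. Without siNRCP array 1 it was 9932, of which 4980 were higher, and these 9932 included the 781 in the same direction. Of the 48 named genes that passed, CCNA1 and SRSF7 passed whichever array was left out, and MMP1, LIPA and PSAT1 in 5 of the 6 such fits. Among the largest increases, GANAB, ANKRD11, OSBPL5, B4GALT1, ZNF45 and TUFT1 passed in 1 of the 6. PRSS23 and ZNF845 passed in 2, and ZW10 and TM4SF1 in 3. The remaining large decreases were no firmer, with CCL20, IFT25 and SERPINA1 in 1, CXCL8 and CA2 in 2, and BNIP3 in 3. The number of named genes that no longer passed was 43, 42 and 42 without sicontrol array 1, 2 and 3, and 0, 29 and 39 without siNRCP array 1, 2 and 3. Because separate cultures are not stated for the replicates, the p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

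Glycolysis genes were lower in siNRCP as a group. The 23 measured genes of the list had a median change of -0.31 log2 (camera adjusted p = 1.5e-05; adjusted p = 0.19 with an estimated correlation), with medians of -0.51, -0.39 and -0.31 on siNRCP arrays 1 to 3. The aldolase gene ALDOC fell by 1.36 ± 0.21 log2 (SE, n = 3 per group; limma adjusted p = 0.030), GAPDH, the dehydrogenase of the middle of the pathway, by 0.88 ± 0.16 (0.047), and the isomerase gene GPI by 0.72 ± 0.12 (0.033). These 3 passed over all probes and 0 rose, and 11 fell when adjusted over the list alone. The other GAPDH probes read -0.98 (0.080) and -0.93 (0.098). Among the glycolysis genes chosen for naming, the glucose transporter gene SLC2A1 did not pass at -0.48 ± 0.10 log2 (0.081), nor did the hexokinase gene HK2 at -0.85 ± 0.26 (0.19), ALDOA at -0.99 ± 0.24 (0.10) or the kinase gene PGK1 at -0.29 ± 0.11 (0.30). The second probes of HK2 (-0.77 ± 0.19, 0.11) and PGK1 (-0.49 ± 0.09, 0.051) did not pass either. A second bright ALDOA probe did pass, at -0.88 ± 0.15 (0.040), while a dim one, above background on 1 sicontrol and 3 siNRCP arrays, read 0.61 ± 0.20 (0.22). The lactate dehydrogenase gene LDHA read -0.25 ± 0.11 (0.41) and -0.24 ± 0.10 (0.35) on probes at 14.58 and 14.56, close to the highest value of 14.70, while its dimmer probe fell by 1.52 ± 0.10 (0.0031). HK1 read 0.29 ± 0.32 (0.77) and turned to -0.06 under median scaling. Without siNRCP array 1, SLC2A1 (-0.42, adjusted p = 0.013), HK2 (-0.55, 0.0063), HK1 (0.66, 0.0068), ALDOA (-1.28, 1.9e-06) and TALDO1 (-0.96, 8.7e-06) passed. In that fit 9932 of all 47231 probes passed, so a pass there says little of glycolysis in particular. Of the glycolysis list, 3 genes passed in it as higher and 11 as lower.

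The pentose phosphate list, which branches from glycolysis, did not pass (9 genes, camera adjusted p = 0.25), although 4 of its genes fell when adjusted over the list alone and 0 over all probes. TALDO1, its transaldolase, read -0.69 ± 0.21 log2 (limma adjusted p = 0.20). CP, the ceruloplasmin gene, lay at background on all arrays, at 6.22 ± 0.17 (SD, n = 3) in sicontrol and 6.15 ± 0.05 in siNRCP, so a change in it was not detectable here.

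Inflammatory target genes of NF-kB were lower in siNRCP as a list. The list of 24 genes had a median of -0.58 log2 (camera adjusted p = 1.7e-07; adjusted p = 0.19 with an estimated correlation), with medians of -0.39, -0.56 and -0.60 on siNRCP arrays 1 to 3. Of its genes 7 fell and 0 rose over all probes, and 13 fell when adjusted over the list alone. Besides CCL20 and CXCL8, the chemokine gene CXCL2 fell by 1.70 ± 0.25 log2 (SE, n = 3 per group; limma adjusted p = 0.024). The remaining 4 that passed, named after their values were seen, were the cytokine genes TNF (-1.59 ± 0.15, 0.0075), IL6 (-1.55 ± 0.26, 0.038), IL1A (-1.42 ± 0.14, 0.0094) and IL1B (-1.21 ± 0.19, 0.031). The immediate early list, transcription factors and phosphatases induced by growth signals, had a median of -0.10 over 23 genes (camera adjusted p = 0.039; adjusted p = 0.37 with an estimated correlation). Its only gene to pass over all probes was DUSP1, a phosphatase that switches off MAP kinases, which fell by 0.78 ± 0.12 (0.030), and 6 fell when adjusted over the list alone. That list did not pass without sicontrol array 1 (-0.06, 0.10), siNRCP array 1 (-0.17, 0.15) or siNRCP array 2 (-0.13, 0.075), and its median was -0.19 without sicontrol array 2 and -0.16 without siNRCP array 3. Its adjusted p ranged from 0.0025 to 0.17 over the 17 other settings run with the preset correlation.

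The interferon response list had a median of -0.11 log2 over 50 genes (camera adjusted p = 0.011; adjusted p = 0.50 with an estimated correlation). IRF1, an interferon-induced transcription factor, was its only gene to pass over all probes and fell by 0.66 ± 0.09 log2 (SE, n = 3 per group; limma adjusted p = 0.019), and 2 fell when adjusted over the list alone. The list did not pass without sicontrol array 2 (-0.07, 0.10) or without siNRCP array 1 (-0.05, 0.11), and its median was -0.19 without sicontrol array 1. Its adjusted p ranged from 0.00015 to 0.11 over the 17 other settings run with the preset correlation.

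Hypoxia and HIF1 target genes were lower in siNRCP. The list of 22 genes had a median of -0.31 log2 (camera adjusted p = 3.7e-05; adjusted p = 0.29 with an estimated correlation), with medians of -0.57, -0.20 and -0.23 on siNRCP arrays 1 to 3. Of its genes 5 fell and 1 rose over all probes, and 7 fell and 1 rose when adjusted over the list alone. BNIP3 fell by 1.98 ± 0.16 log2 (SE, n = 3 per group) and ADM, the gene of the vasodilator peptide adrenomedullin, by 1.31 ± 0.19 (limma adjusted p = 0.0059 and 0.023). STC2, a secreted glycoprotein also held by the ATF4 list, fell by 0.96 ± 0.16 (0.039). The other two, named after their values were seen, were DDIT4, an inhibitor of mTOR signalling (-0.95 ± 0.17, 0.047), and EGLN3, an oxygen-sensing hydroxylase that was not above background on the siNRCP arrays. The gene that rose was ERO1A, an oxidase of the endoplasmic reticulum that forms disulfide bonds, by 1.31 ± 0.22 (0.038).

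Genes of mitosis made up the only list of the 32 to pass upward. The 43 measured genes of G2/M and mitosis had a median of 0.37 log2 (camera adjusted p = 3.7e-05; adjusted p = 0.34 with an estimated correlation), with medians of 0.24, 0.40 and 0.50 on siNRCP arrays 1 to 3, and 0.13 under median scaling. Over all probes 3 rose and 0 fell, and 10 rose when adjusted over the list alone. TPX2, a spindle assembly factor, rose by 1.03 ± 0.12 log2 (SE, n = 3 per group; limma adjusted p = 0.012) and BIRC5, which encodes survivin, by 0.84 ± 0.13 (0.025). CDCA8, a partner of survivin in the chromosomal passenger complex and named after its value was seen, rose by 0.79 ± 0.12 (0.031). Without siNRCP array 1, 23 of the 43 genes passed as higher and 8 as lower. The list of G1/S and DNA replication did not pass (39 genes, camera adjusted p = 0.38). In it the replication licensing gene CDT1 rose by 0.64 ± 0.08 (0.015), and 3 rose and 3 fell when adjusted over the list alone.

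Cholesterol synthesis genes were lower in siNRCP. The list of 20 genes had a median of -0.19 log2 (camera adjusted p = 0.0079; adjusted p = 0.27 with an estimated correlation), with medians of -0.25, -0.13 and -0.21 on siNRCP arrays 1 to 3. Over all probes 4 fell and 0 rose, and 6 fell when adjusted over the list alone. The sterol reductase gene TM7SF2 fell by 1.22 ± 0.16 log2 (SE, n = 3 per group; limma adjusted p = 0.018) and the isomerase gene IDI1 by 1.16 ± 0.16 (0.020). The other two, named after their values were seen, were HMGCS1, an early enzyme of the pathway (-1.01 ± 0.10, 0.0087), and EBP, a sterol isomerase that was not above background on the siNRCP arrays. Without siNRCP array 1 the list's median was -0.26, with 5 genes passing as higher and 7 as lower, and the list did not pass (adjusted p = 0.11), within a range of 0.00012 to 0.11 over the 17 other settings run with the preset correlation. Of the 13 lists that passed camera with its preset correlation, 0 passed with an estimated correlation, and 2 passed fry, which tests whether a list's genes move on balance in 1 direction: NF-kB (adjusted p = 0.042) and cholesterol synthesis (0.042). The estimated correlation was near the preset 0.01 for glycolysis (0.01) and cholesterol synthesis (0). It was far above it for oxidative phosphorylation (0.67), the proteasome (0.67) and ribosomal proteins (0.58). For the other lists that passed it lay between 0.03 and 0.23. With an estimated correlation, camera also takes its degrees of freedom from the 6 arrays rather than from the number of genes, which weakens the test. A failure under that setting is therefore no sign by itself of genes that move together, as glycolysis and cholesterol synthesis show.

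Lists of the mitochondria and of protein turnover had lower medians on siNRCP arrays 2 and 3 than on siNRCP array 1. The oxidative phosphorylation list of 34 genes had a median of -0.51 log2 (camera adjusted p = 7.9e-06; adjusted p = 0.57 with an estimated correlation), with 0.11, -0.84 and -0.92 on siNRCP arrays 1 to 3. On sicontrol arrays 1 to 3 its medians were -0.20, 0.14 and 0.02. None of its genes passed over all probes (0, also when adjusted over the list alone), with COX5A at -1.06 ± 0.37 log2 (SE, n = 3 per group; limma adjusted p = 0.25) and NDUFA8 at -1.25 ± 0.36 (0.16), 2 genes below the list's median that were chosen after their values were seen. Without siNRCP array 1 the list's median was -0.89 and 29 genes fell, but the list did not pass camera with an estimated correlation (adjusted p = 0.54). Without siNRCP array 3 the list's median was -0.33. Each array's score on the main axis of spread among the sicontrol arrays was used as a covariate, chosen after the data had been seen. With it the list's median was -0.19 (camera adjusted p = 0.0020). That p does not show that the list stands apart from the axis, because the axis was taken from the same sicontrol arrays. It also rests on the preset correlation of 0.01, where the estimate for this list was 0.67 without the covariate. Arrays within each group also differed by gene span, the genomic length of a gene, in a check chosen after the data had been seen. Across 11550 named genes above background, siNRCP arrays 2 and 3 minus array 1 had a Spearman rho of 0.42 with span, sicontrol array 1 minus arrays 2 and 3 had 0.26, and siNRCP minus sicontrol had 0.21. Genes are not independent replicates, so no p is given. The TCA cycle list of 19 genes had a median of -0.26 (camera adjusted p = 0.012; adjusted p = 0.37 with an estimated correlation), with -0.11, -0.48 and -0.19 on the siNRCP arrays, and 3 fell when adjusted over the list alone and 0 over all probes.

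Cytosolic ribosomal proteins had a median of -0.29 log2 over 36 genes (camera adjusted p = 0.011; adjusted p = 0.72 with an estimated correlation), with 0.23, -0.48 and -0.64 on siNRCP arrays 1 to 3 and -0.22, 0.25 and 0 on sicontrol arrays 1 to 3. Of these genes 0 passed over all probes, and the 1 that passed when adjusted over the list alone was higher. The list did not pass without sicontrol array 2 (-0.15, adjusted p = 0.16), siNRCP array 2 (-0.18, 0.16) or siNRCP array 3 (-0.14, 0.26), and without siNRCP array 1 its median was -0.57. Proteasome subunits had a median of -0.32 over 27 genes (camera adjusted p = 0.039; adjusted p = 0.72 with an estimated correlation), with 0.26, -0.55 and -0.49 on the siNRCP arrays and 0 genes passing, also when adjusted over the list alone. That list did not pass without sicontrol array 1 (0.082), sicontrol array 3 (0.083), siNRCP array 2 (-0.14, 0.51) or siNRCP array 3 (-0.16, 0.27), and without siNRCP array 1 its median was -0.56. With the score on the sicontrol axis of spread as a covariate, neither the ribosomal list (-0.04, 0.94) nor the proteasome list (-0.13, 0.57) passed. Over the 17 other settings run with the preset correlation the adjusted p ranged from 1.4e-08 to 0.94 for the ribosomal list and from 4.1e-07 to 0.57 for the proteasome list.

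NRF2 antioxidant genes had a median of -0.25 log2 over 20 genes (camera adjusted p = 0.018; adjusted p = 0.34 with an estimated correlation), with -0.07, -0.35 and -0.25 on siNRCP arrays 1 to 3 and 0 genes passing, also when adjusted over the list alone. Histone genes had a median of -0.27 over 19 genes (camera adjusted p = 0.015; adjusted p = 0.56 with an estimated correlation), with 0.02, -0.27 and -0.36 on the siNRCP arrays. The variant histone gene H3-3B fell by 0.78 ± 0.08 log2 (SE, n = 3 per group; limma adjusted p = 0.011), as the only histone gene to pass over all probes, and 2 fell when adjusted over the list alone. Without siNRCP array 2 the NRF2 list (adjusted p = 0.054) and the histone list (-0.17, 0.075) did not pass, nor did the histone list without siNRCP array 3 (-0.17, 0.071), and without sicontrol array 2 its median was -0.16. With the score on the sicontrol axis of spread as a covariate, the histone list did not pass (-0.05, 0.27), and the NRF2 median was -0.15 (0.026). Over the 17 other settings run with the preset correlation the adjusted p ranged from 0.0025 to 0.056 for the NRF2 list and from 0.0022 to 0.27 for the histone list.

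**Figure D2:**
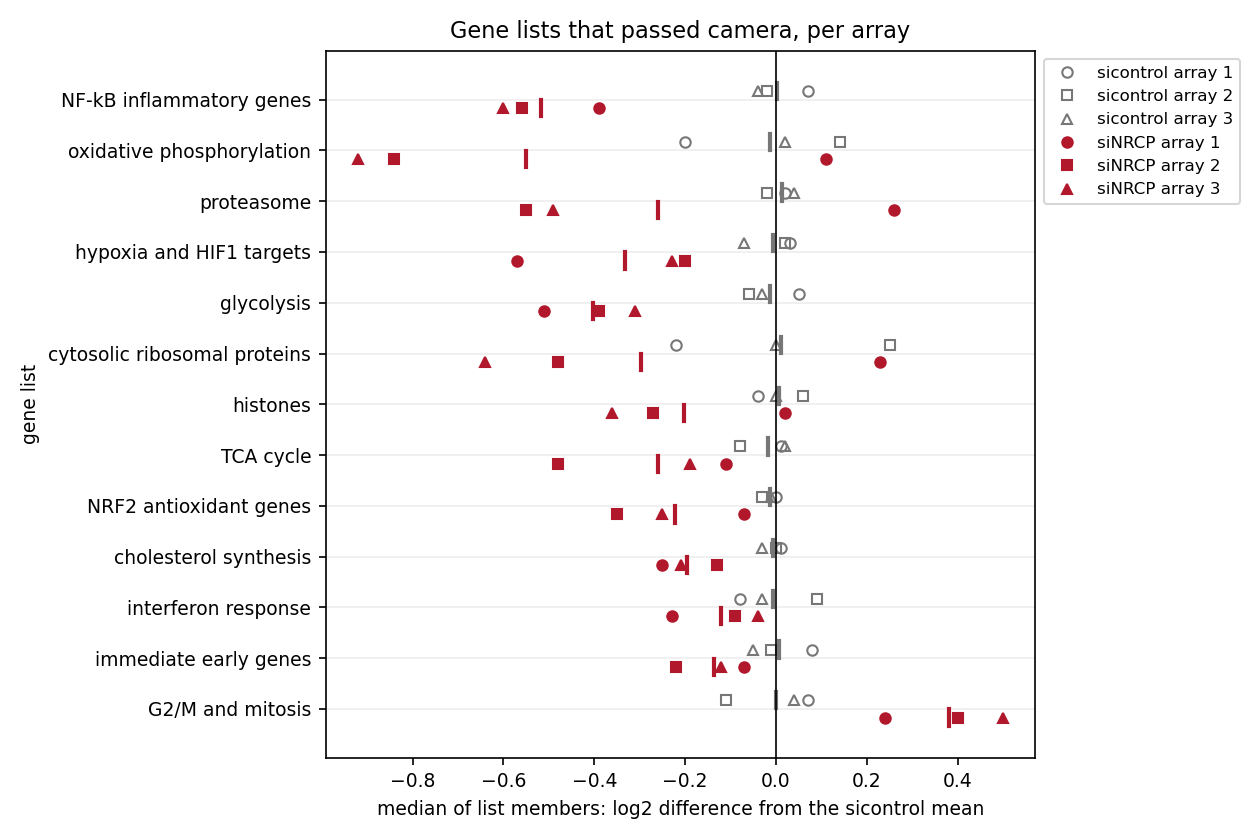
Median log2 difference from the sicontrol mean for each of the 13 gene lists that passed camera, with 1 point per array and a vertical bar at the mean of each group of 3. The NF-kB list lay at -0.39, -0.56 and -0.60 on the siNRCP arrays, while the oxidative phosphorylation list lay at 0.11 on siNRCP array 1 and at -0.84 and -0.92 on the other two.

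Among the lists that did not pass camera, some genes still changed over all probes. Of the 22 p53 targets (camera adjusted p = 0.080), CDKN1A, which encodes the cell cycle inhibitor p21, fell by 1.48 ± 0.15 log2 (SE, n = 3 per group; limma adjusted p = 0.0094), and the stress gene GADD45A fell by 1.42 ± 0.25 (0.045; -1.25 ± 0.32 and 0.13 on its second probe), and 2 fell when adjusted over the list alone. Of the 31 ATF4 and amino acid response genes (0.49), the serine synthesis gene PSAT1 fell by 1.47 ± 0.08 (0.0019), STC2 fell as above, ATF5, a transcription factor named after its value was seen, fell by 0.70 ± 0.12 (0.039), and the glutamine transporter gene SLC1A5 rose by 1.0 ± 0.15 (0.028). Adjusted over the list alone, 3 of these genes rose and 5 fell. In the unfolded protein response (27 genes, 0.92) the co-chaperone gene DNAJB9 fell by 1.01 ± 0.09 (0.0075), the only one by either adjustment. Of 29 ribosome biogenesis and MYC target genes (0.82), NOLC1, a nucleolar protein, rose by 1.51 ± 0.11 (0.0041) and ODC1, the ornithine decarboxylase, by 0.75 ± 0.11 (0.027), with 3 higher and 1 lower when adjusted over the list alone. Of 26 lysosome and autophagy genes (0.16), the autophagy conjugation genes ATG12 and ATG5 fell by 1.15 ± 0.18 and 0.74 ± 0.10 (0.029 and 0.019), with 4 lower and 1 higher when adjusted over the list alone.

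In the mesenchymal and invasion list (24 genes, camera adjusted p = 0.12), MMP1 fell as above, and the urokinase gene PLAU fell by 1.13 ± 0.16 log2 (SE, n = 3 per group; limma adjusted p = 0.020), with 2 genes lower by either adjustment. In the epithelial and ovarian carcinoma list (24 genes, 0.38), MSLN, the surface antigen mesothelin, fell by 0.65 ± 0.12 (0.043), and 2 genes fell when adjusted over the list alone. Of 23 apoptosis regulators (0.60), BID, which links death receptors to mitochondria, fell by 0.57 ± 0.09 (0.031), while its other probes did not pass, and 2 genes fell when adjusted over the list alone. Of 21 genes of fatty acid synthesis and oxidation (0.23), the dehydrogenase gene ACADM fell by 0.65 ± 0.11 (0.035), and 6 fell when adjusted over the list alone. No gene passed over all probes (0) among 21 TGF-beta and YAP targets (0.051), 20 iron and copper handling genes (0.78), 19 heat shock genes (0.39) or 13 genes of the RNA interference machinery (0.38). When adjusted over the list alone, 1 TGF-beta and YAP target rose, 1 iron and copper gene rose and 1 fell, and 0 passed in the other two.

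Most markers of other cell types lay at background, and their lists did not pass camera. Of 17 leukocyte markers (adjusted p = 0.95) 3 lay above background, of 15 fibroblast markers (0.95) 6, of 12 endothelial markers (0.92) 1, and of 9 mesothelial markers (0.27) 2, among them MSLN, which the epithelial list also holds. Apart from MSLN, 0 of these markers passed over all probes, and 1 fibroblast marker rose when adjusted over the list alone. Some lists differed in sign between median, mean and test. Ribosome biogenesis had a median of -0.07 and a mean of 0.04 with an upward test, and the unfolded protein response a median of 0.03, a mean of -0.03 and an upward test. Iron and copper handling had a median of 0.01 and a mean of -0.07 with a downward test, and fibroblast markers -0.01 and 0.01 with a downward test. The leukocyte (0.02 and 0.01) and endothelial lists (0.01 and 0) also had a downward test, and apoptosis regulators had a median of 0 and a mean of -0.05.

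The siNRCP arrays were not alike. Over the probes above background, siNRCP arrays 2 and 3 correlated at 0.992 with each other, and siNRCP array 1 at 0.937 and 0.947 with them and at 0.973 to 0.981 with the sicontrol arrays, which correlated at 0.987 to 0.994 among themselves. These are correlations across probes, which are not independent replicates. The number of probes more than 1 log2 unit from the sicontrol mean was 330 on siNRCP array 1, 2219 on array 2 and 1659 on array 3, against 17, 44 and 1 for each sicontrol array set against the other two. MMP1 (-2.67, -2.94 and -2.99 on siNRCP arrays 1 to 3), SRSF7 (-2.11, -2.0 and -1.88) and PSAT1 (-1.42, -1.55 and -1.43) were displaced about alike on every siNRCP array, while GANAB (1.49, 2.71 and 2.81) and CCL20 (-1.72, -3.08 and -2.91) were displaced less on array 1. Of the 781 changed probes 55.3% were lower. Under median scaling, where the median of the probes above background shifted by -0.127 log2, 254 probes passed and 83.1% of them were lower. No list changed direction under it (0 of 13), but some medians grew in size by over 1.5 times, to -0.62 for glycolysis, -0.61 for ribosomal proteins, -0.55 for the proteasome, -0.53 for hypoxia, -0.50 for the TCA cycle, -0.39 for NRF2, -0.37 for cholesterol synthesis and -0.27 for both the interferon and the immediate early list.

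**Figure D3:**
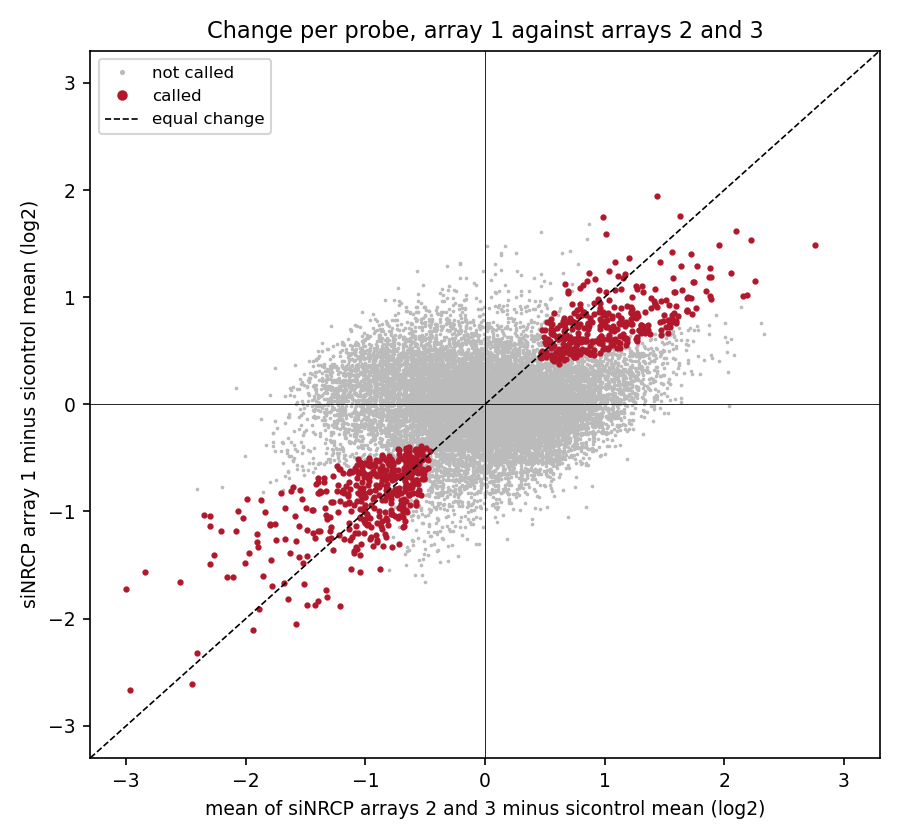
Displacement of each probe above background from the sicontrol mean, in log2 units, on siNRCP array 1 against the mean of siNRCP arrays 2 and 3, with the 781 changed probes in red and a dashed line of equal change. Across these probes the correlation was 0.19, whereas arrays 2 and 3 correlated at 0.93.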

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

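The background filter and the covariate for the axis of spread among the sicontrol arrays were chosen only after the data had been seen. The count of 781 changed probes (349 higher, 432 lower) moved by over 1.5 times to 254 (43 and 211) under median scaling, 468 (209 and 259) with trend and robust options, 8162 (4179 and 3983) with array weights and 1728 (788 and 940) with the covariate. With the replicate number as a block limma gave 0 (0 higher and 0 lower), with 4893 probes at an unadjusted p under 0.05. Across probes, same-number deviations correlated at -0.64, -0.43 and -0.20 and the others at -0.53 to 0.63. The main spread of the arrays was thus not shared by number. A weaker pairing is not excluded, because the deviations within a group depend on each other and follow that main spread. Leaving out 1 array gave 11 to 9932 changed, 0 to 4980 higher and 10 to 4952 lower, and 8 to 13 lists. With no background correction, an offset of 16, cyclic loess, the series matrix values, the mean of a gene's probes and the background filter the count lay between 553 and 973. The 553 came with the mean of a gene's probes, which counts each named gene once, so its unit differs from that of the 781. The 13 lists became 0 with an estimated correlation and 2 with fry, and glycolysis no longer passed (adjusted p = 0.19 and 0.055), its median of -0.315 being the same by construction; under the other settings with all arrays 10 to 19 lists passed, and with or without all arrays the glycolysis list stayed lower and past the threshold, with medians of -0.616 to -0.217. Of the 48 named genes that passed, 25 were lost under median scaling, 15 with trend and robust options, 48 with the block, and 0 to 10 under the other settings that kept all arrays. Some named genes that had not passed were gained with all arrays kept. SLC2A1 passed under cyclic loess, array weights and the covariate, and HK2 and ALDOA under array weights and the covariate. TALDO1 passed under array weights, and LDHA with the mean of a gene's probes. HK1, which did not pass, reversed to -0.058 under median scaling and -0.088 with the covariate, and CP, which lay at background on all arrays so that its sign carries no meaning, read -0.152 to 0.014 without 1 array. The cause was not tested. A setting without a detection filter was the same as the one reported, and a detection p under 0.01 was not run because the intensity table carries no detection p-values. All 781 changed probes were among the 20027 of 47231 above background, so nothing is said of transcripts at background.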

Other observations

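The zinc finger list, all tests on it, the covariate for an axis of spread, the trend with gene span and the 3 tests on the split of the siNRCP arrays were chosen only after the pattern they concern had been seen, whereas the splits of the arrays were planned.

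Genes named as zinc finger proteins (ZNF), most of which encode DNA-binding repressors, were higher in siNRCP. Pseudogenes with such names were kept, and ZNF252P, ZNF788P, ZNF542P and ZNF702P were among those that rose. Of 483 measured ZNF genes 54 rose and 2 fell at a limma adjusted p under 0.05, with a median of 0.19 log2. Of the 371 above background 14.6% rose, with a median of 0.30 and medians of 0.15, 0.41 and 0.42 on siNRCP arrays 1 to 3, against 1.81% (202 of 11187) of the other genes above background, whose median was 0.01 (Fisher's exact test, p = 1.9e-29, odds ratio 9.26, treating genes as independent). The 4 examples besides ZNF845 and ZNF45, chosen after their values were seen, were ZNF616 (1.61 ± 0.12 log2, SE, n = 3 per group; limma adjusted p = 0.0045), ZNF317 (1.48 ± 0.20, 0.020), ZNF227 (1.44 ± 0.13, 0.0075) and ZNF426 (1.42 ± 0.12, 0.0075). Camera gave p = 5.5e-14 for the 483 genes and p = 0.11 with an estimated correlation. The median stayed above 0 under median scaling (0.10), cyclic loess (0.18), the series matrix values (0.15) and no background correction (0.14), with 12, 75, 42 and 40 genes higher. The counts of ZNF genes that rose are limited by the number of probes that passed as higher at all. That number was 0, 3 and 1 without sicontrol arrays 1 to 3, and 0 with the replicate number as a block. It was 4980, 71 and 11 without siNRCP arrays 1 to 3.

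An axis of spread that also separates the sicontrol arrays is not excluded as a source of the ZNF pattern. With each array's score on that axis as a covariate in limma, the median of the 483 genes was 0.15, against 0.19 without it. That cannot show that the pattern stands apart from the axis, because the axis was taken from the same sicontrol arrays. The scores of siNRCP arrays 2 and 3 (34.5 on both) also lay beyond those of the sicontrol arrays (-25.2 to 25.8). Gene span and expression level do not account for the ZNF pattern. The median of 0.30 for the 371 genes lay at percentile 100 of 10000 random lists matched for both, whose highest median was 0.09. Signal shared between the similar sequences of ZNF genes was not tested and stays open. So does a biological response to siNRCP, since the design holds 1 siRNA against 1 control and a direct effect of the siRNA on other transcripts was not tested.

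The siNRCP arrays split, with array 1 nearer to the sicontrol arrays than arrays 2 and 3. A mislabelled sicontrol array is argued against by 330 probes more than 1 log2 unit from the sicontrol mean on siNRCP array 1, against at most 44 on a sicontrol array. Of 1853 probes, 92 were displaced on array 1 by at least 0.8 of the change on arrays 2 and 3, and 609 in the opposite direction. The spread of the sicontrol arrays around the median ratio of 0.14 gave 7 in place of the 92. That 7 may be too low, because the probes had passed a fit that held the sicontrol arrays but not siNRCP array 1. Passing favours a small spread among the arrays in the fit. The comparison therefore does not decide whether the response on array 1 was uniformly weaker. An axis of spread shared with the sicontrol arrays may contribute: across probes, 2 contrasts that share no array correlated at 0.64, and both rose with gene span (Spearman rho 0.42 and 0.26 across genes). Arrays 2 and 3 of siNRCP also had the lowest mean raw intensity, at 373 and 486. It was 554 on siNRCP array 1 and 555 to 563 on the sicontrol arrays, and a link to the split was not tested. Culture state, RNA handling and a biological difference in response between the siNRCP samples stay open, and the span trend does not tell them apart.

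The 6 arrays allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 781 changed probes and the highest of the others 0, so that 1 of the 10 splits gave as many. Every other split mixes siNRCP and sicontrol arrays in both groups, which puts their difference into the spread within groups. The contrast of 781 with 0 is therefore no measure of chance. For gene lists the real split gave 13 and the highest of the others 7, again 1 of the 10 splits with as many.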
